A study of Drosophila melanogaster with 4 samples.

How the data were processed

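RNA was profiled by sequencing from 4 cell populations sorted by flow cytometry from Drosophila melanogaster embryos, with 1 library per population. Per the labels, the caudal visceral mesoderm (CVM) cells and the cells that remained after their removal came from embryonic stages 10 to 13, and the hemocytes (HC) and their remaining cells from stages 12 to 16. Per the labels' protocols, total RNA was purified on Qiagen RNeasy columns with DNase digestion on the column, and libraries followed the Illumina protocol. The submitters' processing notes name Bowtie 0.12.7, TopHat 1.3.3, Cufflinks 1.3.0, Cuffdiff and the genome build BDGP5. The annotation release, the read counts and the depth of each library were not given in the sources used here.

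The material analysed was 2 gene tables in Cuffdiff's layout, named CVM and HC, each with the same 14794 genes. Which table belongs to which population rests on that name. Per the file headers, each table compares conditions called q1 and q2, and neither name occurs in a sample's labels. The conditions were therefore left unassigned, every fold change is given as q2 relative to q1, and the 4 columns of FPKM per condition were not used in any computation. These columns were looked at once, to check that the fold is q2 over q1 and on the scale the header names. Whether q1 plays the same part in both tables is not given in the sources used here.

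Fold changes were taken from the deposited tables: per the file headers they are on the log2 scale for CVM and the natural log (ln) scale for HC, and the latter were divided by the natural log of 2. The score column used was the authors' test statistic. Genes with an infinite fold are listed at 0 in 1 condition, and are counted but given no fold. The p-value and q-value of each gene are the authors', per the file headers, and their call is a q-value under 0.05. For HC, 568 q-values lay above 1, the highest at 1.03, so that column was treated as a score whose low end is read as q. The p-value of each tested gene equalled the normal p of the authors' statistic within 0.001, and the sign of that statistic was opposite to the fold. The ratio of log2 fold to statistic therefore gave the standard error that the authors' test implied, with a median of 0.54 log2 units in CVM and 0.72 in HC. That error describes reads of 2 libraries and holds no variation between samples.

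A gene counted as measured when its status was OK and its fold finite, which held for 9580 genes in CVM and 10088 in HC. In HC a further 316 genes of status OK had a fold and a statistic of exactly 0 and were left out after this had been seen. The median log2 fold of the HC table was 0.62 without them and 0.57 with them. A size rule of at least 2-fold took the place of a test, since 1 library per group allows none, and the authors' calls stand beside it as a comparison of 2 libraries. On simulated folds drawn with the implied errors for the 9580 CVM genes, the size rule found 93% of genes changed by 2 log2 units and 100% of those changed by 4, and 12.3% of unchanged genes passed it by noise. For the 10088 HC genes the shares were 88%, 99% and 18.3%. These shares hold only as far as the implied errors do, and those may be too wide, as described below for CVM. Unchanged HC genes were drawn without the table's median of 0.62.

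The lists of genes, 27 in number, were fixed before the data were examined, and 10 of their members had no matching symbol. They cover caudal and trunk visceral mesoderm, hemocytes, crystal cells, the FGF and PVR pathways, basement membrane, integrins, cadherins, guidance, phagocytosis, immunity, somatic muscle, heart, neurons, glia, epidermis, trachea, midgut, salivary gland, fat body, germ cells, the cell cycle, heat shock, ribosomal proteins and the mitochondrial genome, and 1 further list is not reported here. Some genes sit on more than 1 list, such as Tig, Glt and Pxn (hemocyte and basement membrane), crq, drpr and Sr-CI (hemocyte and phagocytosis) and Mef2 (caudal visceral mesoderm and somatic muscle). Each list's median was ranked among the medians of 10000 random lists of the same size, matched on implied standard error in 20 bins. That matching was chosen after the data had been seen, in place of the planned matching on expression. The percentile describes these libraries and is no test. Numbers of unchanged genes past 2-fold by noise were summed from the normal tail of each gene's implied error, after the data had been seen.

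Named genes followed a rule set before the data were examined and adapted, before the folds were examined, where it needed FPKM. It took the 12 largest folds in each direction among genes called by the authors, leaving out CG and CR numbers and symbols of small nucleolar, small nuclear, transfer, micro and 5S RNAs, histones and mitochondrial genes, where 12 and 8 above 10 FPKM had been planned. It also took up to 2 members of each list in each direction, a set of 10 fixed markers, and the 10 genes called in both tables with the largest smaller fold for each pair of directions. These pairs stood in for the planned choice of 5 genes in each direction by the difference between the tables. Families in the closing section were chosen after the folds had been seen.

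Gene symbols, identifiers and loci are those of the tables (BDGP5, written from 1). Genes that overlap share a locus in them: the 14794 genes lie in 11650 loci and 9560 have a locus to themselves. Reads of overlapping genes may have been divided between them, and the strand handling is not given in the sources used here, so such genes are named as sharing a locus. The reference annotation in hand was BDGP6, of another build, and gave transcript lengths and no coordinates. Of the gene identifiers, 13460 matched it. Alternatives were centring on the median fold, all genes whatever their status, no noncoding, histone or mitochondrial features, a 4-fold rule, and the authors' calls. Genes listed at 0 in 1 condition, an implied standard error of at most 0.5, and genes with their own locus were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.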

Results

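Gene expression was compared within 2 pairs of embryonic cell populations, to examine which genes are expressed in migrating cells and in the rest of the embryo. The caudal visceral mesoderm migrates along the gut primordium and later forms longitudinal gut muscle, and hemocytes are the blood cells that disperse through the embryo. Each was set against the other cells of embryos of the same stages, stages 10 to 13 for CVM and 12 to 16 for HC. Each population had 1 library, so no difference has a replicate check, and the authors' calls compare 2 libraries, not conditions. The depth of the libraries is unknown, and the authors' tests imply a median standard error of 0.54 log2 units per gene in CVM and 0.72 in HC, without variation between samples. The tables name the conditions q1 and q2 only. Directions are therefore given as higher in q1 (a negative log2 fold) or higher in q2 (a positive one), and neither is assigned to the sorted cells.

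In the authors' deposited table for CVM, the markers of caudal visceral mesoderm were higher in q1. HLH54F, a bHLH transcription factor that specifies this tissue (FBgn0022740, chromosome 2R, 13644922 to 13648022, BDGP5), had a log2 fold of -6.04 and a q-value listed as 0. The forkhead factor croc had -2.74 (q-value 1.64e-06), the FGF receptor htl -1.93 (3.18e-11) and its adaptor stumps -1.23 (0.000531) in the authors' deposited table. Of the 10 genes on the caudal visceral mesoderm list, 9 were at least 2-fold higher in q1 and the same number were called in the authors' deposited table. The list's median was -1.97, below all but 0.01% of unmatched random lists. Only byn lay in the other direction, at 0.72, and it was not called (q-value 0.67 in the authors' deposited table).

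Muscle genes lay on the same side. Of 19 somatic muscle genes, 15 were at least 2-fold higher in q1, all 15 of the calls on this list were in that direction, and the median was -2.85. Myosin heavy chain (Mhc) had -5.73 and the troponin C gene TpnC47D -5.63 in the authors' deposited table, while nau, a myogenic bHLH factor that shares its locus, had 1.23 and was not called. Basement membrane genes gave 7 of 14 at least 2-fold higher in q1 and 6 called, with a median of -0.93. Among them, Tig (tiggrin, an integrin ligand, at a shared locus) had -5.13 and trol (perlecan) -3.78 in the authors' deposited table. For integrins and cell-matrix adhesion 7 of 16 were at least 2-fold higher in q1 and 7 were called, with a median of -0.84, at percentile 0.01. Vinculin (Vinc) had -2.80 and the tensin gene by -2.51 in the authors' deposited table.

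Other lists also held genes higher in q1 of the CVM table. Hemocyte genes gave 5 of 12, with 4 called and a median of -0.74. Sr-CI, a scavenger receptor, had -1.77, srp, a GATA factor, -0.86 and Pxn (peroxidasin, shared locus) -1.26, all called in the authors' deposited table. Of the other markers crq had -1.01, Hml -0.63, Pvr -0.08 and gcm 0.45, none of them called in the authors' deposited table, and crq, Hml and gcm share their loci with other genes. Fat body genes gave 4 of 5 (median -1.15, 2 called), led by the apolipophorin gene Rfabg at -3.47 in the authors' deposited table. The trunk visceral mesoderm list had a median of -0.88 with 3 called. There bin, a FoxF factor, had -2.29 and was called, and Alk had 1.07 and was not, in the authors' deposited table. The median of this list was 0.03 over genes with a locus of their own. Phagocytosis genes had a median of -0.41 (2 of 14 called), immune genes -0.30 (3 of 12) and heat shock genes -0.25 (4 of 18), with Hsp67Bc at -3.50 and Hsp26 at -3.12 in the authors' deposited table. The FGF pathway had 3 of 15 called and a median of -0.02. Guidance genes had 4 of 20 called, led by beat-IIb at -7.18 in the authors' deposited table, and a median of -0.09. Germ cell genes had a median of -0.27, with osk at -3.68 and ovo at 1.06, both called in the authors' deposited table.

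Genes higher in q2 of the CVM table changed less. All 23 cell cycle genes measured lay above 0, and their median of 0.55 was higher than those of all 10000 random lists, although 2 of 23 reached 2-fold and 2 were called. RnrS, a subunit of ribonucleotide reductase, had 1.15 in the authors' deposited table. Neuronal genes had a median of 0.62 with 1 of 12 called, the homeodomain factor pros at 1.04 in the authors' deposited table. This median was -0.07 over genes of every status. Heart genes were divided: tup had 1.27, and Doc2 and Doc1 -2.09 and -1.89, all called in the authors' deposited table, around a median of 0.45. Epidermal genes had 2 of 10 called, grh at 1.38 and sdt at 0.93 in the authors' deposited table, and a median of 0.26. Tracheal genes went both ways, with trh at 1.20 and Gasp, a chitin-binding protein, at -2.57 in the authors' deposited table. Their median was 0.29, and -0.89 over genes with a locus of their own. The crystal cell list had 1 of 4 called higher in q2 and a median of 0.92, and glia 1 of 7 and 0.14. On 3 lists with medians above 0 the calls were higher in q1. These were midgut (1 of 7 called, median 0.33), salivary gland (1 of 6, 0.09), and cadherins and cell-cell adhesion (2 of 13, 0.20). The calls were betaTry at -4.30, PH4alphaSG1 at -4.81, and Fas2 at -0.99 with Fas3 (shared locus) at -0.94 in the authors' deposited table. Glia turned to -0.26 among genes with an implied standard error of at most 0.5, and salivary gland to -0.16 among genes with their own locus. The PVR pathway had no call among 4 genes and a median of 0.16, ribosomal proteins 1 of 82 called higher in q2 and -0.12, and the mitochondrial genome 1 of 27 called higher in q2 and 0.48.

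Across the CVM table, 1689 genes were at least 2-fold higher in q1 and 439 in q2, with a median log2 fold of 0.00 (0.0047) over all 9580. The authors' deposited table called 898 genes, 8.96% of those of status OK. With a finite fold, 813 of these were higher in q1, with a median size of 2.82 log2 units, and 73 in q2, with a median size of 1.07 in the authors' deposited table; 12 more were listed at 0 in q2. With genes known only by a CG number left out, the largest called folds higher in q1 were those of the serine protease Jon99Fi (-8.53), Osi20 (-8.45), tey (-7.84), Ipod (-7.57), Jon99Fii (-7.55), the pigment transporter w (-7.54), Osi9 (-7.51), beat-IIb (-7.18), Osi14 (-7.15), beat-IIa (-6.90), the mucin Muc55B (-6.87) and Osi19 (-6.46) in the authors' deposited table. Those higher in q2 were the segment factors inv (1.44), slp2 (1.42) and en (1.27), with grh (1.38), drm (1.38), Ubx (1.36), ab (1.32), HLHmgamma (1.29), tup (1.27), BobA (1.25), grn (1.24) and D (1.23) in the authors' deposited table. Ubx and ab share their loci with other genes, and reads of the near-identical Jon99Fi and Jon99Fii may have been divided between them. If no gene differed, the implied errors alone would carry about 593 genes past 2-fold in each direction, more than the 439 found in q2. With fewer genes found than noise alone would give, these errors may be too wide to set a floor for q2. The count by size in q2 was therefore not told apart from noise. Both called and at least 2-fold higher in q2 were 42 genes in the authors' deposited table.

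In the authors' deposited table for HC, hemocyte genes were higher in q1. The GATA factor srp, which specifies blood cells (FBgn0003507, chromosome 3R, 11811923 to 11829807, BDGP5), had a log2 fold of -3.25 and a q-value of 8.28e-12. Pxn had -6.35, Sr-CI -6.29, the phagocytic receptor crq -4.55 and Pvr, the PDGF/VEGF receptor, -3.24, and all were called in the authors' deposited table. Pxn and crq share their loci with other genes. The transcription factor gcm (shared locus) had -1.47 (q-value 0.146) and Hml, a clotting protein at a shared locus, 1.34 (0.332), neither called in the authors' deposited table. Of 12 hemocyte genes, 11 were at least 2-fold higher in q1 and 9 were called, and the median was -3.24.

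The median of the HC table itself lay at 0.62, so medians of its lists are also given relative to it. Crystal cell genes had a median of -7.88 (-8.50 relative to the table), with 3 of 4 called. The Runx factor lz had -7.25, and the prophenoloxidase genes proPO-A1 (shared locus) and CG8193 -8.76 and -8.51 in the authors' deposited table; prophenoloxidase genes are alike in sequence, so the division of reads among them is uncertain. Basement membrane genes had 12 of 14 at least 2-fold higher in q1, 9 called and a median of -3.43 (-4.05). The collagen IV chains Cg25C and vkg had -7.84 and -7.23 in the authors' deposited table. Phagocytosis genes had 11 of 12 at least 2-fold higher in q1, 6 called and a median of -1.93 (-2.55). Heat shock genes had 12 of 19, 5 called and a median of -1.46 (-2.07), with Hsp26 at -4.24 and Hsp22 (shared locus) at -3.17 in the authors' deposited table. Integrins and cell-matrix adhesion had 2 of 16 at least 2-fold higher in q1 and 3 in q2, or 8 and 1 after centring. Their median was -0.28 (-0.89), with scb at -2.08 and by at 1.79, both called in the authors' deposited table. Immune genes had 5 of 12 at least 2-fold higher in q1, 4 called and a median of -0.48 (-1.09), among them spz at -2.86 in the authors' deposited table. Fat body genes had 1 of 4, or 3 after centring, 1 called and a median of -0.63 (-1.25). The mitochondrial genome had 8 of 18, or 13 after centring, 1 called and a median of -0.79 (-1.41).

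Most lists of other tissues had medians above that of the HC table. Cell cycle genes had 22 of 23 at least 2-fold higher in q2, 20 after centring, 11 called and a median of 1.91 (1.29). RnrL had 2.20 and the replication helicase subunit Mcm3 (shared locus) 2.22 in the authors' deposited table. Heart genes had 9 of 10, also after centring, 7 called and a median of 2.19 (1.57), with tin at 2.53 and svp (shared locus) at 2.37 in the authors' deposited table. Trunk visceral mesoderm genes had 9 of 9, or 7 after centring, 6 called and a median of 1.96 (1.34), among them the ligand jeb at 2.86 and its receptor Alk at 2.17 in the authors' deposited table. The caudal visceral mesoderm list had 7 of 10, or 3 after centring, and a median of 1.42 (0.80). There Mef2 had 1.89 and htl 1.47, both called, HLH54F 1.55, croc 2.11 and stumps 1.27, none of these last called, and zfh1 -2.41 and scb -2.08, both called, in the authors' deposited table. Somatic muscle had 11 of 18, or 6 after centring, 3 called and a median of 1.21 (0.59), with nau at 2.63 in the authors' deposited table. Neurons had 10 of 14, or 6 after centring, 5 called and a median of 1.39 (0.77), with the neuroblast factors wor at 2.10 and dpn at 1.92 in the authors' deposited table. Epidermis had 8 of 10 (5 after centring), 3 called and a median of 1.61 (0.99). Cadherins and cell-cell adhesion had 9 of 12 (6 after centring), 3 called and 1.61 (0.996). Trachea had 6 of 7 (4 after centring), 4 called and 1.68 (1.06), and midgut 5 of 5 (2 after centring), 2 called and 1.51 (0.89). Salivary gland had 4 of 6 (3 after centring), 2 called and 1.58 (0.96), and germ cells 6 of 10 (4 after centring), 2 called and 1.46 (0.84). Called in the other direction were Gasp (trachea) at -2.20 and CrebA (salivary gland) at -1.43 in the authors' deposited table. Guidance genes had 11 of 22, or 7 after centring, 3 called higher in q2 and a median of 0.98 (0.37), with NetB (shared locus) at 1.91 and Sema-1a (shared locus) at -1.80 in the authors' deposited table. The FGF list had 7 of 15, or 5 after centring, 3 called and a median of 0.73 (0.11), and the PVR list 1 of 4 in each direction, or 1 in q1 and 0 in q2 after centring, with Pvr the only call, and 0.74 (0.12). Glial genes had 1 of 7 called higher in q1 and 2 in q2, and ribosomal protein genes 0 of 83 called. Their medians, at 0.51 and 0.15, turned to -0.10 and -0.46 after centring.

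The HC table held 1344 genes at least 2-fold higher in q1 and 3570 in q2, so 27.4% of these were higher in q1. After centring on the median the counts were 2231 and 1610, or 58.1% higher in q1. The authors' deposited table called 1354 genes, 12.6% of those of status OK, with 596 higher in q1 and 690 in q2 at a finite fold (46.3% in q1). Another 22 called genes were listed at 0 in q2 and 46 at 0 in q1 in the authors' deposited table. Among called genes with a name other than a CG number, the largest folds higher in q1 were those of Pde1c (-9.25), proPO-A1 (-8.76), Cg25C (-7.84), the lipocalin Karl (-7.76), nAcRbeta-21C (-7.53), w (-7.36), Hexo2 (-7.29), lz (-7.25), vkg (-7.23), Ppn (papilin, -7.12), alpha-Est1 (-6.94) and NtR (-6.63) in the authors' deposited table. Higher in q2 were Ts (10.33), 7SLRNA (5.19), lbe (4.81), a small noncoding RNA (4.79), IM14 (4.31), Nos (3.73), ssp5 (3.66), Her (3.65), nAcRalpha-34E (3.48), Cpr11A (3.35), amos (3.32) and yl (3.28) in the authors' deposited table. Of these, Pde1c, proPO-A1, Hexo2, Ts, Nos and nAcRalpha-34E share their loci with other genes. If no gene differed, the implied errors alone would carry about 941 genes past 2-fold in each direction of this table. That number takes no account of the table's median of 0.62, and the implied errors may be too wide, as in CVM. It therefore sets no floor for either direction.

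**Figure D1:**
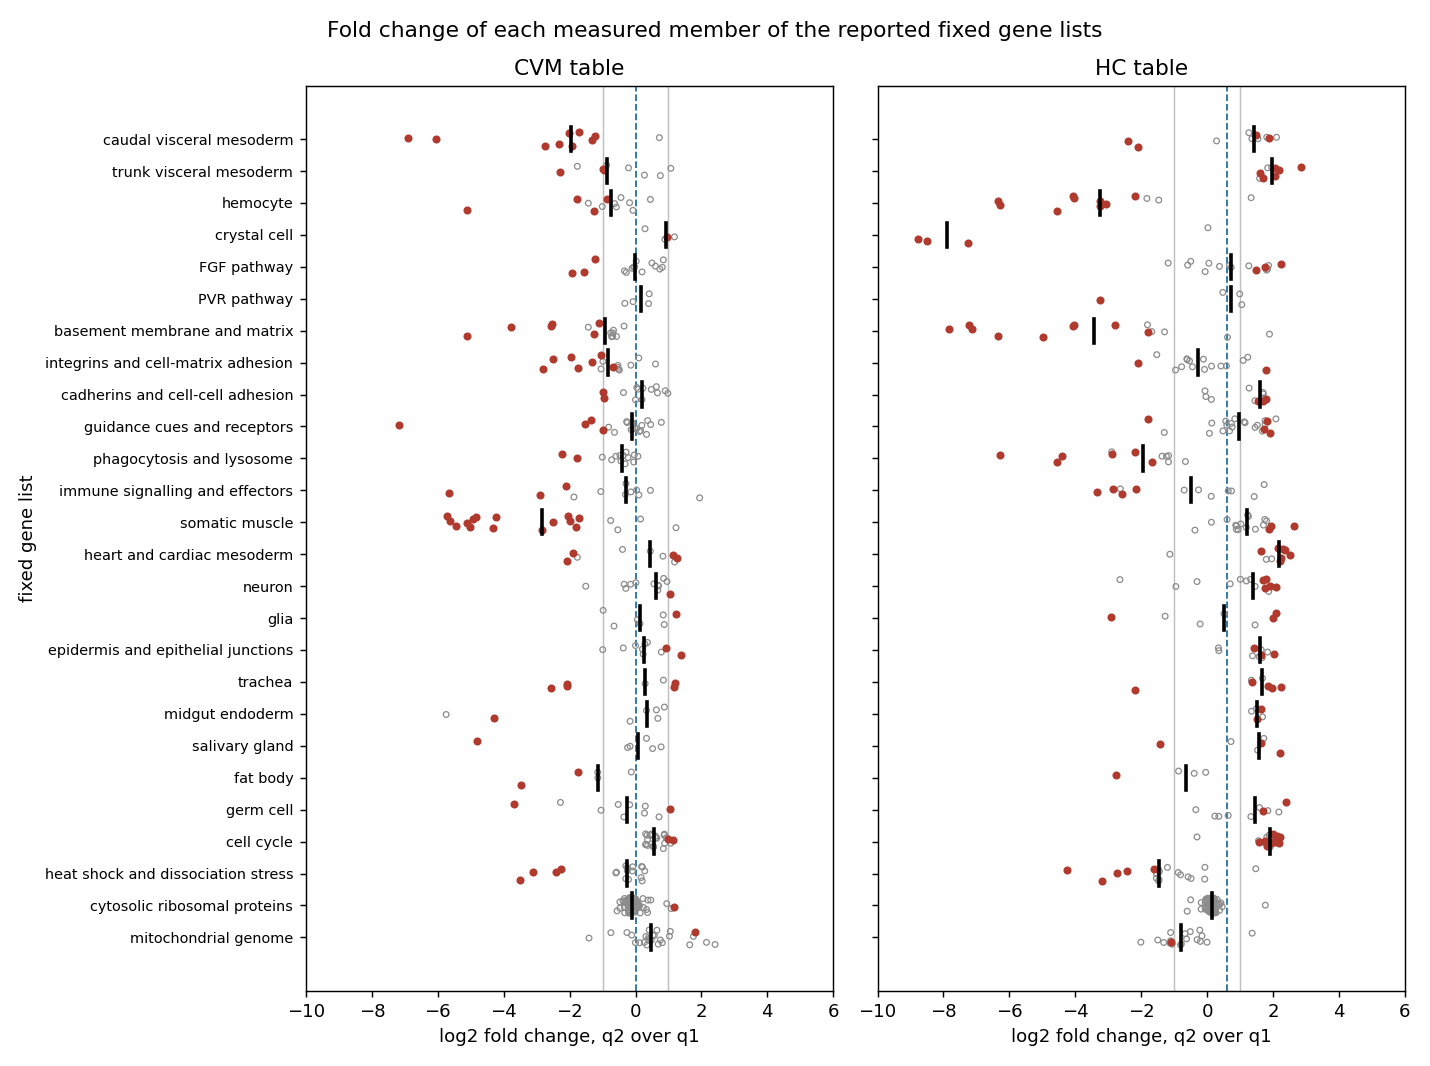
Each point is a measured member of a fixed gene list that is reported, placed by its log2 fold change (q2 over q1) in the CVM table (left) and the HC table (right). Red points were called by the authors, black bars are list medians, grey lines mark 2-fold and the dashed blue line is the median of the table (0.62 in HC), and the caudal visceral mesoderm list has medians of -1.97 and 1.42.

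The tables were then set side by side over 8927 genes measured in both. The comparisons share no library, and whether q1 has the same role in each is not given. Markers of the sorted population lay on the q1 side of both tables. At least 2-fold higher there were 9 of 10 caudal visceral mesoderm genes in CVM and 11 of 12 hemocyte genes in HC. Placed by these markers, q1 would hold the sorted cells in both, although no label names it. Higher in q1 in both were 487 genes by the 2-fold rule, where independent lists would share 183, and 166 genes called in both, where they would share 42.2. Among these were w (-7.54 in CVM and -7.36 in HC), nimB4 (-4.34 and -4.80), Osi19 (-6.46 and -4.18), Tig (-5.13 and -4.06), fat-spondin (-3.66 and -5.33), Tsp42Ed (-3.62 and -3.72), Cyp6a23 (-3.39 and -4.70), Tsp29Fa (-3.33 and -5.01), Mec2 (-3.25 and -6.56) and olf186-M (-3.24 and -3.52) in the authors' deposited table for each. Tig, fat-spondin and olf186-M share their loci with other genes. Higher in q2 in both were 259 genes against 123 under independence, and 36 called against 4.62. Called there were slp2, grh, drm, Ubx, ab, tup, en, D, Gli and trh, with folds in HC from 1.65 for tup to 2.45 for drm in the authors' deposited table.

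Opposite directions held fewer genes by the 2-fold rule than independence gives. Higher in q1 of CVM and q2 of HC were 371 genes against 514, or 166 against 220 after centring, and 42 called against 52.2. Called in both tables, and leading by the smaller of their folds, were yl, the yolk protein receptor (-4.98 and 3.28), 7SLRNA (-3.04 and 5.19), BicC (-3.09 and 2.90), dhd (-4.49 and 2.55), the homeodomain factor H2.0 (-4.72 and 2.36), salt (-2.23 and 2.55), nvy (-2.33 and 2.17), Doc2 (-2.09 and 2.22), bin (-2.29 and 2.06) and gol (shared locus, -2.02 and 2.03) in the authors' deposited table for each. Higher in q2 of CVM and q1 of HC were 18 genes against 43.9, or 26 against 74.3 after centring, with 0 called in both. Across genes, Pearson's r was 0.32 and Spearman's rho 0.47, and r was 0.42 over the 244 genes called in both; genes are not independent replicates.

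**Figure D2:**
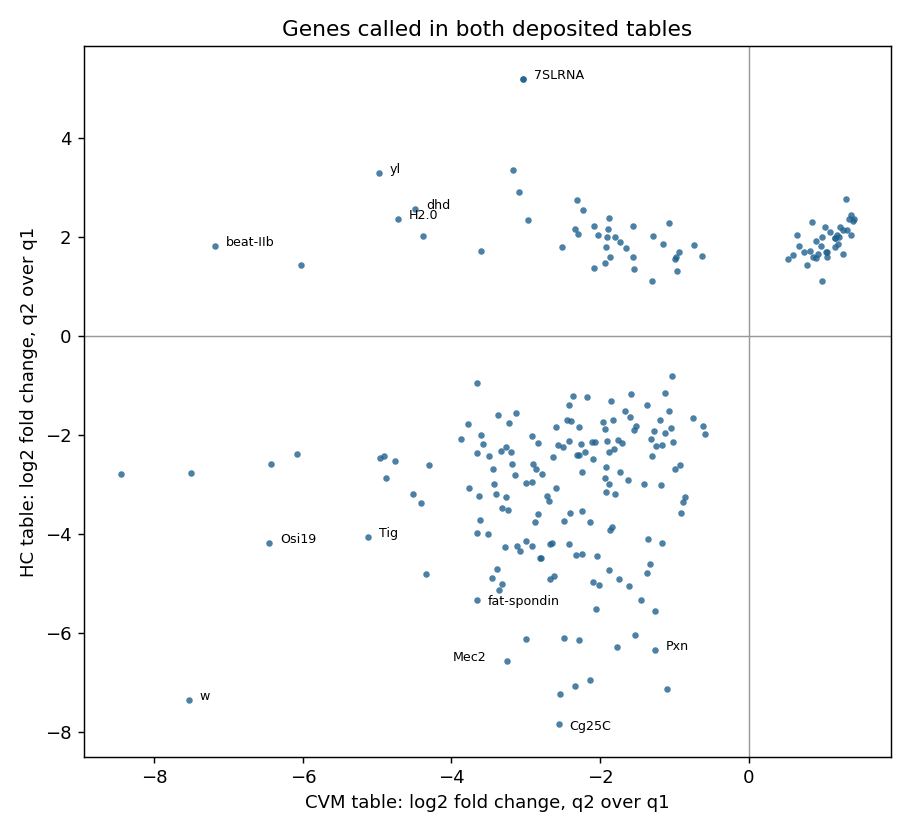
Each of the 244 points is a gene called in both tables, with its log2 fold change (q2 over q1) in CVM on the horizontal axis and in HC on the vertical axis. Lower left holds 166 genes, upper left 42, upper right 36 and lower right 0.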

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

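The settings for genes listed at 0 in 1 condition, for implied standard error and for loci, and the authors' calls across both tables, were chosen after the data had been seen. Counts below are for CVM q1, CVM q2, HC q1 and HC q2, then for both tables as q1 with q1, q1 with q2, q2 with q1 and q2 with q2 (CVM given before HC). The 2-fold rule gave 1689, 439, 1344 and 3570, then 487, 371, 18 and 259. With a 4-fold rule they were 861, 61, 613 and 718, then 133, 49, 3 and 7, and by the authors' calls 813, 73, 596 and 690, then 166, 42, 0 and 36. An implied standard error of at most 0.5 left 250, 82, 86 and 142, then 32, 10, 0 and 6, with fewer genes counted, and r across genes was 0.471 where it had been 0.32; the cause was not tested. Genes with a locus of their own, again fewer, gave 254 for CVM q2, 890 and 2169 for HC, and 170 for q2 with q2. Centring gave 2231 and 1610 for HC and 166 for q1 with q2, since it subtracts the HC median. The count for q2 with q1 became 38 over genes of every status and 34 with genes listed at 0, as more genes enter. Other counts stayed within 1.5 times.

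Of 243 recomputed list medians 7 changed sign, each given beside its list. Centring moved 34 of 271 values of named genes by more than the implied standard error, and 0 called values changed sign. Pseudocounts of 0.1 and 5, minimum FPKM of 0, 1 and 10, upper-quartile rescaling and random lists matched on expression were not run, because they need the FPKM columns. The depth of the libraries is unknown. No paired analysis was possible because each population had 1 library and no replicate number came from the labels.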

Other observations

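The families below, and the tests of epidermal RNA, of reads shared between paralogs, of older embryos and of a single scaling factor, were chosen after the results had been seen. Several gene families lay outside the fixed lists. Of 11 Osiris genes measured in CVM, which encode secreted or membrane proteins of epithelia, 9 were at least 2-fold higher in q1, 8 were called and the median was -5.54. In HC 6 of 10 were, 4 were called and the median was -1.22 (-1.84 after centring). The Jonah serine proteases of the gut had 11 of 12, 9 called and a median of -4.25, with Jon99Cii at -6.27 in the authors' deposited table. Of 70 listed cuticle proteins of the Cpr family, 23 were measured in CVM. Of these, 15 were at least 2-fold higher in q1 and 3 in q2, with 3 called, all in q1, and a median of -1.79. Their folds were imprecise, with implied standard errors from 0.82 (Cpr78E) to 1.67 (Cpr30B). Tweedle cuticle proteins had 6 of 12, 3 called and -2.31, tetraspanins 14 of 25, 7 called and -1.49, and cytochrome P450 genes 25 of 44, 14 called and -1.36. In HC the median was -0.05 for Cpr (-0.66 after centring; 2 called in q1 and 1 in q2) and -0.43 for Tweedle genes (-1.05; 1 called in q1). There the median of tetraspanins was 0.29 and that of cytochrome P450 genes 0.32, and both turned to -0.33 and -0.30 after centring. By the 2-fold rule in HC, 7 of 27 tetraspanins were higher in q1 and 10 in q2. Cytochrome P450 genes had 16 of 54 higher in q1 and 11 in q2. Of the HC calls with a finite fold, 4 of 4 among tetraspanins and 11 of 12 among cytochrome P450 genes were higher in q1. Cyp4p1 (shared locus) was also called in HC (q-value 9.79e-28), listed at 0 in q1, and Tsp74F was called in CVM (q-value 0.0326), listed at 0 in q2, in the authors' deposited table for each. Nicotinic receptor subunits went both ways. In CVM 2 of 4 were at least 2-fold higher in q1 and 1 in q2, with 0 called and a median of -0.74. In HC 1 of 7 was higher in q1 and 4 in q2, with a median of 1.32 (0.70 after centring), and those called were nAcRbeta-21C at -7.53 and nAcRalpha-34E (shared locus) at 3.48 in the authors' deposited table.

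Nimrod genes, relatives of phagocytic receptors, were at least 2-fold higher in q1 of HC in 7 of 8 cases, with 5 called and a median of -4.25 (-4.87 after centring), among them nimC3 at -5.11 and nimB1 at -4.67 in the authors' deposited table, both at shared loci. In CVM 4 of 4 were at least 2-fold higher in q1, with 1 called and a median of -1.77. Segment and selector factors had 8 of 20 at least 2-fold higher in q2, 6 called there and a median of 0.91 in CVM, and 18 of 19, 13 called and 2.10 in HC (1.48 after centring). In CVM eve had -4.16 and was called, and Abd-B had -0.34 and was not, in the authors' deposited table. Transcripts laid down in the oocyte were at least 2-fold higher in q1 of CVM in 6 of 7 cases (5 called, median -3.56) and at least 2-fold higher in q2 of HC in 5 of 7 (3 called, median 1.85, or 1.23 after centring). This family shares osk, pgc and nos with the germ cell list. The embryonic patterning gene bcd (shared locus) had -3.56 in CVM, where it was called, and -2.58 in HC, where it was not, in the authors' deposited table.

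Among cuticle and gut families of the CVM table, 8 of 11 Osiris, 9 of 12 Jonah, 3 of 23 Cpr and 3 of 12 Tweedle genes were called higher in q1. RNA from epidermis of the same stages would bring epidermal regulators and junction genes too. Their list had a median of 0.259 (95% interval across genes -0.37 to 0.93), with 2 called higher in q2 and 0 in q1. Of its 10 genes 8 lay above 0, and knk (-0.99) and kkv (-0.37, shared locus), neither called in the authors' deposited table, lay below. If q1 held the sorted cells, as the markers place it, q2 would hold the epidermis itself. This list then cannot decide whether q1 had some epidermal RNA. Reads shared between paralogs stayed open, because the 68.1% of 47 Jonah, Cpr and Tweedle genes at least 2-fold higher in q1 belong to the pattern itself and have close paralogs too. Whether RNA from older embryos or other cell types contributed could not be decided. The cell cycle list had a median of 0.55, which a difference in cell type alone could also give. Transcripts laid down in the oocyte lay towards q1 of CVM, with a median of -3.56 and 5 of 7 called. In HC they lay towards q2, with a median of 1.85. They were not tested against age and are not counted here as a sign of older embryos. The labels give both populations the same stages and name no difference in age. Age and cell type cannot be told apart here. A difference between the populations themselves remained open and untested.

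The gene w was among the largest folds in q1 of both tables. The other eye pigment genes had a median of -0.33 (-0.329) in CVM, with 4 of 11 at least 2-fold higher in q1, and of -0.33 in HC (-0.95 after centring), with 3 of 12, so as a group they lay far from w. Called among them were cn (-3.52) and ltd (-2.40) in CVM and ltd (-1.72) in HC in the authors' deposited table for each. Within 50 kb, 2 other genes were measured, and the lower of the medians was -0.62 (-0.623, in CVM). They had -1.11 and -0.14 in CVM and -0.49 and 0.96 in HC. These lay far from w, although the lower in CVM passed 2-fold in the same direction. With 2 genes, a change of the region cannot be decided. Since w is widely used as a marker on transgenes, such a copy could be a source of its reads, and this was not tested because no construct is named in the labels.

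Most genes lay above 0 in the HC table. A single scaling factor would move abundant housekeeping genes alike. Ribosomal protein genes had a median of 0.15 (0.154, 95% interval across genes 0.11 to 0.18) against 0.62 for all genes. That interval describes spread among genes and holds no variation between samples. The difference cannot exclude such a factor, because ribosomal protein genes may themselves differ between the cell types compared. In CVM, with a table median of 0.0047, their median was -0.12 and 63 of 82 lay below 0. Gene length was unrelated to fold, with Spearman's rho at -0.01 (-0.0135) across 9251 genes. A difference in the mixture of cell types may remain, and no test addressed it.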
